A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

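RNA of 12 chemostat cultures was measured on Affymetrix Yeast Genome 2.0 arrays, 1 array per culture, with 3 cultures in each of 4 groups made by 2 strains and 2 temperatures. Per the labels' protocols, samples were chilled quickly on ice, RNA was extracted with a kit and biotin-labelled cRNA was hybridised. The deposited values are 1 linear intensity per probe set and array, and were used as the authors deposited them. Array medians ran from 329 to 371 and upper quartiles from 645 to 771, both higher at 30 °C than at 15 °C. The summary and normalization methods are not given in the sources used here. The lowest intensity on every array was 10, which was treated as a floor. Values at or below the 1st percentile of an array were set to that percentile, which the floor already held.

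Probe sets were named through the platform annotation, with 12 symbols updated through the RefSeq gene table of assembly R64, which was used for names and gene order only. Of 5900 probe sets, 5498 had 1 gene, 0 had several and 402 were unnamed here. The probe set with the highest mean over all arrays represented a gene, which left 5449 genes, 47 of them with several probe sets. The probe sets of a gene gave opposite calls for 2 genes in the strain comparison at 30 °C and for 0 in each other comparison. Probe sets that share sequence between near-identical genes stood for 117 genes. Probe sets of a second yeast species, planned as a measure of background, were not used here. In their place the filter on dim genes removed genes with a mean in the lowest 25% of probe sets.

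Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, 1 coefficient per group, no block), with 8 residual degrees of freedom and 2.22 prior degrees of freedom. The 5 comparisons were 15 °C against 30 °C in each strain, EC1118 against CEN.PK113-7D at each temperature, and the difference of the 2 temperature effects. All adjusted p-values for genes are two-sided limma values with Benjamini-Hochberg adjustment over the genes of a comparison, with a threshold of 0.05. Folds are ratios from means of log2 values. Where any array of the dimmer group was at the floor, the fold is a lower bound against the floor, and no fold is given where both groups were there on all arrays. Means of intensity are given with the SD over 3 arrays, and log2 changes with the limma standard error.

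Gene lists with at least 4 measured members, 47 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the residuals passed 0 lists in any comparison, so each list is given with that adjusted p too. fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, was an alternative. Groups, comparisons, gene lists, the rule for named genes and the alternatives below, except the one named as added, were fixed before the data were examined. The named genes were the 10 with the highest and the 10 with the lowest change per comparison among those past the threshold, without overlap between groups (not asked of the interaction) and with no array of the higher group at the floor. Up to 4 members with the smallest adjusted p per described list and a fixed panel were added.

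The alternatives were a replicate block, a fit of the 2 compared groups alone, quantile normalization, median centring, the filter on dim genes, a pseudocount of 50, eBayes with trend and robust options, the mean of a gene's probe sets, all probe sets as separate features, multi-copy and subtelomeric families left out, and each array left out in turn. Replicate numbers met the condition for pairing, a correlation of deviations above 0.1 in every pair, only between the strains at 15 °C (0.48, 0.32 and 0.39), from the data and not from the labels. With 1 array left out, the fit pooled the spread of all groups. The omission of both arrays that stood apart from their groups was added after seeing the data.

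The fit was tested on simulated data with 50 genes changed at each log2 size of 0.5, 1, 2 and 3 among 5449 genes. For temperature in CEN.PK113-7D it recovered 27, 49, 50 and 50 of them by rising size and called 7 unchanged genes. For temperature in EC1118 it recovered 35, 48, 50 and 50 and called 11 unchanged genes. The strain comparison at 15 °C gave 34, 45, 50 and 50 with 8 unchanged genes called, and that at 30 °C gave 35, 47, 50 and 50 with 5. For the interaction 18, 44, 48 and 50 were recovered and 8 unchanged genes were called. In each comparison 0 of 47 simulated lists passed with none changed, and the 1 shifted list was recovered. The changed genes were drawn from those with a mean intensity above 50 (mean of log2 values), and no floor was applied. The recovery counts therefore do not cover genes near the floor. The simulated noise was independent between genes, so it could not test how the list test behaves where genes of a list vary together.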

Results

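Transcript levels were measured in 2 strains of the budding yeast Saccharomyces cerevisiae, each grown at 15 °C and at 30 °C. CEN.PK113-7D is a haploid laboratory strain of mating type a, and EC1118 is a diploid industrial wine strain. All cultures were anaerobic, nitrogen-limited steady-state chemostats, in which the dilution rate of 0.05 per h sets the growth rate, so that the temperatures were compared at one growth rate. Each of the 4 groups held 3 biological replicates, each hybridised to its own Affymetrix Yeast Genome 2.0 array. The deposited table held a linear intensity for 5900 probe sets on each of 12 arrays, with a floor of 10 that held 1.90% to 3.31% of the probe sets of an array. Array medians ran from 329 to 353 at 15 °C and from 356 to 371 at 30 °C, so the scale of the arrays went with temperature. Replicates correlated with r from 0.975 to 0.994 in log2 intensity across the 5449 genes analysed, which are not independent. The number of arrays limits the precision.

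**Figure D1:**
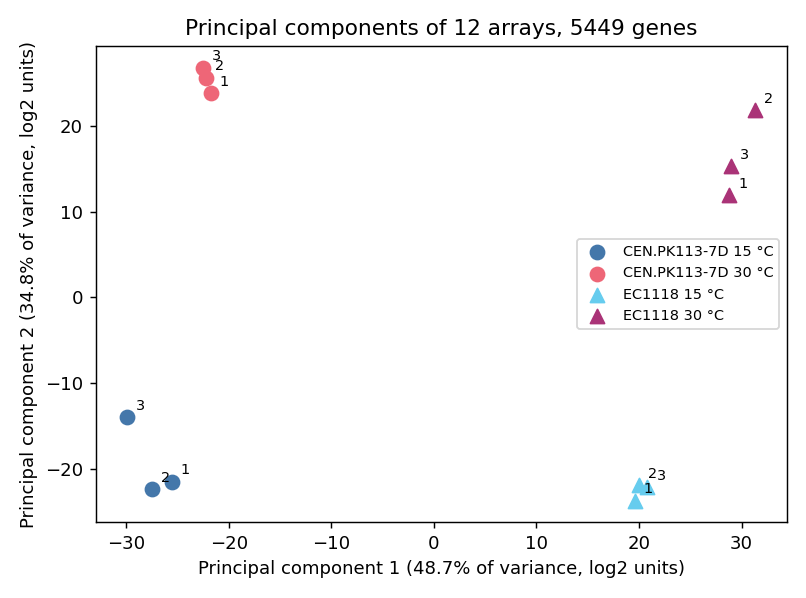
First and second principal components (48.7% and 34.8% of the variance) of log2 intensity, with 1 point per array, the shape giving the strain, the colour the group and the digit the replicate number. The first component separated the strains and the second the temperatures, and CEN.PK113-7D replicate 3 at 15 °C and EC1118 replicate 2 at 30 °C lay farthest from their groups.

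The first comparison asked which transcripts of CEN.PK113-7D differed between 15 °C and 30 °C at the same growth rate. PDR12, which encodes the plasma membrane pump for weak organic acids, had an intensity of 2391 ± 182 (SD, n = 3) at 15 °C and 226 ± 89.6 (n = 3) at 30 °C, which was 11.1-fold higher in the cold (log2 change 3.47 ± 0.31 SE, adjusted p = 1.28e-05). EFM6, a methyltransferase of translation elongation factor 1A, rose 14.3-fold (log2 change 3.83 ± 0.27), and ARE2, an acyltransferase that esterifies sterols, rose 6.73-fold (log2 change 2.75 ± 0.43). Without replicate 3 at 30 °C, where ARE2 read 211 against 53.0 and 60.5, the ARE2 fold was 10.4. Among genes that fell in the cold were FUI1, the uridine permease (17.6-fold lower, log2 change -4.14 ± 0.12), and DIP5, a permease for glutamate and aspartate (16.0-fold lower). PUT1, the first enzyme of proline degradation, was 14.1-fold lower. The hexose transporters HXT5 and HXT2 were 15.7-fold and 11.1-fold lower. HSP30, a plasma membrane stress protein, fell by 3.77 on the log2 scale, from 753 ± 199 to 54.6 ± 11.6. FLO11, a cell surface flocculin, was 7.90-fold lower (log2 change -2.98 ± 0.08).

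In all, 3185 of 5449 genes passed the threshold in CEN.PK113-7D (limma, Benjamini-Hochberg), 1189 higher and 1996 lower at 15 °C, and 476 of them changed at least 2-fold (159 higher, 317 lower). The 3 values at one temperature did not overlap the 3 at the other for 62.8% of genes, where chance gives 10%. The split between higher and lower depended on the scaling: the median log2 change over all genes was -0.11, and with every array centred on its median 1578 genes were higher and 1575 lower, while quantile normalization gave 1656 higher and 1525 lower. Most list medians in this strain are therefore given relative to the median of all genes, and are called relative. List medians not called relative, here and in EC1118, are plain medians of log2 change.

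Genes for making ribosomes rose together in CEN.PK113-7D at 15 °C. Of 143 ribosome biogenesis genes, 120 rose and 2 fell (123 and 3 adjusted over the list alone), with a median of 0.86 log2 relative to all genes. The list test gave adjusted p = 4.91e-30 with the preset correlation and adjusted p = 0.310 with an estimated correlation. NSR1, a nucleolar protein of rRNA processing known to respond to cold, rose 4.90-fold (log2 change 2.29 ± 0.11), and the RNA helicase HAS1 rose 2.92-fold. For subunits of RNA polymerases I and III, 18 of 27 rose and 0 fell (19 and 0 adjusted over the list alone, relative median 0.56), RPA49 among them at 2.39-fold (list test adjusted p = 1.26e-06, and adjusted p = 0.308 with an estimated correlation). Cytosolic ribosomal proteins shifted less, by a relative median of 0.30, with 72 of 128 higher and 3 lower (72 and 3 adjusted over the list alone; list test adjusted p = 7.83e-13, and adjusted p = 0.308 with an estimated correlation). Of the members, 25 shared a probe set with a near-identical copy. For mitochondrial ribosomal proteins, 32 of 74 rose and 4 fell (31 and 4 adjusted over the list alone, relative median 0.33, list test adjusted p = 9.42e-06, and adjusted p = 0.550 with an estimated correlation). With centred arrays 45 mitochondrial ones rose and 1 fell, and 98 and 1 cytosolic ones. Of 20 RNA helicases and cold-linked translation factors, 11 rose and 0 fell (11 and 0 adjusted over the list alone), DBP2 by 3.04-fold, with a list test adjusted p = 0.000363 and adjusted p = 0.308 with an estimated correlation.

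Stress and storage genes were lower in CEN.PK113-7D at 15 °C. Of 35 heat shock proteins and chaperones, 31 fell and 1 rose (31 and 1 adjusted over the list alone, relative median -0.81, list test adjusted p = 1.24e-06, and adjusted p = 0.310 with an estimated correlation). The small chaperone HSP26 was 9.32-fold lower (log2 change -3.22 ± 0.50) and the disaggregase HSP104 2.69-fold lower (-1.43 ± 0.13). Of 51 targets of the stress regulators Msn2 and Msn4, 35 fell and 0 rose (36 and 0 adjusted over the list alone, relative median -1.03, list test adjusted p = 1.26e-06, and adjusted p = 0.644 with an estimated correlation). TMA10 was 10.8-fold lower, and HSP12 measured a log2 change of -1.05 ± 0.54 that missed the threshold (adjusted p = 0.121) but passed it in a fit of the 2 compared groups alone (adjusted p = 0.0232). All 9 measured trehalose genes fell (9 adjusted over the list alone, relative median -0.88, list test adjusted p = 0.000441, and adjusted p = 0.480 with an estimated correlation). TSL1 of the trehalose synthase complex was 4.31-fold lower and the trehalase NTH2 3.69-fold lower. Glycogen genes fell in 10 of 13 cases (10 adjusted over the list alone, relative median -1.09, list test adjusted p = 0.0117, and adjusted p = 0.640 with an estimated correlation), the glycogen synthase GSY2 by 2.49-fold.

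Nitrogen and iron acquisition genes were also lower in CEN.PK113-7D at 15 °C. Of 52 genes under nitrogen catabolite repression, 38 fell and 3 rose (38 and 3 adjusted over the list alone, relative median -0.43, list test adjusted p = 9.42e-06, and adjusted p = 0.453 with an estimated correlation). The urea permease DUR3 was 9.35-fold lower, the amino acid permease AGP1 4.13-fold, the repressor DAL80 3.51-fold and the ammonium permease MEP2 1.49-fold. Amino acid biosynthesis genes went the other way, with 28 of 65 higher and 11 lower (28 and 11 adjusted over the list alone, relative median 0.24, list test adjusted p = 0.000734, and adjusted p = 0.480 with an estimated correlation). LEU9 of leucine synthesis rose 3.66-fold. With centred arrays 7 of these genes were lower, and 6 of the iron regulon described next were higher. In the iron regulon 21 of 33 genes fell and 3 rose (21 and 3 adjusted over the list alone, relative median -0.34, list test adjusted p = 0.0227, and adjusted p = 0.310 with an estimated correlation). The iron uptake oxidase FET3 was at least 8.71-fold lower, with 1 of 3 arrays at 15 °C at the floor, and its partner permease FTR1 5.05-fold lower. Cell wall genes fell in 31 of 50 cases and rose in 2 (32 and 2 adjusted over the list alone, list test adjusted p = 0.000615, and adjusted p = 0.310 with an estimated correlation), with DSE1 4.77-fold lower. Autophagy and vacuolar protease genes fell in 22 of 33 cases (22 adjusted over the list alone, list test adjusted p = 0.00137, and adjusted p = 0.542 with an estimated correlation), ATG11 by 1.78-fold. Of 36 proteasome genes, 20 fell and 0 rose (19 and 0 adjusted over the list alone, list test adjusted p = 0.0117, and adjusted p = 0.480 with an estimated correlation). With centred arrays 11 fell. The proteasome list test did not pass with median centring (adjusted p = 0.132) or quantile normalization (adjusted p = 0.498), nor without both arrays that stand apart, an omission chosen after seeing the data (adjusted p = 0.0518).

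Transcripts of fatty acid synthesis and TIR1 were looked at in both strains. The fatty acid desaturase OLE1 was 1.34-fold lower at 15 °C in CEN.PK113-7D (log2 change -0.43 ± 0.08, adjusted p = 0.00145) and 1.53-fold lower in EC1118 (-0.62 ± 0.08, adjusted p = 0.000182). TIR1, a cell wall mannoprotein known from cold shock, measured -0.50 ± 0.18 in CEN.PK113-7D (adjusted p = 0.0360), a call lost with median centring (adjusted p = 0.111) and quantile normalization (adjusted p = 0.0894), and in a fit of the 2 compared groups alone (adjusted p = 0.0940). It was also lost without CEN.PK113-7D replicate 2 or 3 at 15 °C (adjusted p = 0.0502 and 0.0982; log2 change -0.27 without replicate 3) and without replicate 1 or 2 at 30 °C (0.108 and 0.0695). In EC1118 TIR1 measured -0.10 ± 0.18 (adjusted p = 0.652). Of 18 fatty acid genes, 3 rose and 9 fell in CEN.PK113-7D (3 and 9 adjusted over the list alone), and 5 rose and 9 fell in EC1118 (5 and 9 adjusted over the list alone). That list passed its test in neither strain (adjusted p = 0.454 and 0.920, and adjusted p = 0.796 and 0.977 with an estimated correlation).

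The same comparison in EC1118 asked which transcripts of the wine strain differed between 15 °C and 30 °C. EFM6 rose 11.7-fold in the cold (log2 change 3.54 ± 0.27, n = 3 per temperature, adjusted p = 8.60e-06), and ARE2 rose 5.48-fold. SFG1, a regulator of filamentous growth, rose 8.92-fold, from 122 ± 31.5 to 1069.6 ± 110.0, and the acid phosphatase PHO5 rose 6.30-fold. AZR1, a plasma membrane transporter, was at the floor on all 3 arrays at 30 °C and at 398 ± 273 at 15 °C, at least 34.1-fold higher. The aquaporin AQY1 was 23.0-fold lower at 15 °C (log2 change -4.52 ± 0.60), with 30 °C intensities of 489, 2261 and 1264 in replicates 1, 2 and 3, and 34.8-fold lower without replicate 1 at 30 °C. GIT1, a transporter of glycerophosphoinositol, was 9.28-fold lower, YRO2, a membrane protein, 15.9-fold and DUR3 7.17-fold. HXT5 was 8.91-fold lower, 16.2-fold without replicate 1 at 30 °C and 4.98-fold without replicate 2, whose intensities were 121 and 1283. HSP30 read 919 in replicate 2 at 30 °C, and 61.2 and 83.6 in the others. In this strain 2953 of 5449 genes passed the threshold, 1320 higher and 1633 lower at 15 °C, 414 of them at least 2-fold (146 higher, 268 lower), and the values of 62.7% of genes did not overlap between temperatures (10% by chance). This split turned over with the scaling: 1626 genes were higher and 1393 lower with centred arrays, and 1575 and 1414 with quantile normalization.

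Ribosome biogenesis rose in EC1118 too, with 104 of 143 genes higher and 2 lower (111 and 2 adjusted over the list alone, list test adjusted p = 2.65e-17, and adjusted p = 0.695 with an estimated correlation). Its median log2 change was 0.51, and 0.55 relative to all genes. NSR1 was 2.53-fold higher. RNA polymerase I and III subunits rose in 15 of 27 cases and fell in 1 (15 and 1 adjusted over the list alone, list test adjusted p = 0.00577, and adjusted p = 0.695 with an estimated correlation). Cytosolic ribosomal proteins rose in 54 of 128 cases and fell in 2 (49 and 1 adjusted over the list alone, median 0.12, list test adjusted p = 1.84e-07, and adjusted p = 0.695 with an estimated correlation). Their median relative to all genes was 0.16. Helicases and cold-linked factors rose in 10 of 20 cases and fell in 1 (10 and 1 adjusted over the list alone, list test adjusted p = 0.0107, and adjusted p = 0.695 with an estimated correlation). For amino acid biosynthesis 38 of 65 genes rose and 8 fell (38 and 8 adjusted over the list alone, list test adjusted p = 3.92e-05, and adjusted p = 0.695 with an estimated correlation), with SER1 of serine synthesis 1.80-fold higher.

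All 9 trehalose genes fell in EC1118 at 15 °C (9 adjusted over the list alone, median -1.23, list test adjusted p = 0.000175, and adjusted p = 0.695 with an estimated correlation), TSL1 by 3.97-fold. Msn2 and Msn4 targets fell in 32 of 51 cases and rose in 1 (36 and 2 adjusted over the list alone, median -1.11, list test adjusted p = 9.88e-07, and adjusted p = 0.738 with an estimated correlation), MOH1 by 6.47-fold. Heat shock proteins and chaperones fell in 20 of 35 cases and rose in 3 (20 and 3 adjusted over the list alone, median -0.37, list test adjusted p = 0.0126, and adjusted p = 0.738 with an estimated correlation). With centred arrays 17 fell and 5 rose. Relative to all genes, the medians in EC1118 were -1.20 for trehalose genes, -1.08 for Msn2 and Msn4 targets and -0.34 for heat shock proteins and chaperones. HSP26 was 4.63-fold lower, and 3.06-fold lower without replicate 2 at 30 °C, where it read 1080.4 against 223 and 431. The constitutive chaperone SSA2 was 1.89-fold higher at 15 °C. Genes under nitrogen catabolite repression fell in 28 of 52 cases and rose in 8 (29 and 10 adjusted over the list alone, list test adjusted p = 0.00942, and adjusted p = 0.738 with an estimated correlation). AGP1 fell 5.04-fold, while DCG1 rose 2.82-fold. Autophagy and vacuolar protease genes fell in 21 of 33 cases and rose in 1 (22 and 2 adjusted over the list alone, list test adjusted p = 0.00270, and adjusted p = 0.695 with an estimated correlation), the kinase ATG1 by 2.60-fold.

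Proteasome genes rose in 16 of 36 cases in EC1118 and fell in 3 (16 and 3 adjusted over the list alone, median 0.17, list test adjusted p = 0.0184, and adjusted p = 0.695 with an estimated correlation). The core subunit PUP3 was 1.42-fold higher, while RPN4, the transcription factor of proteasome genes, and the polyubiquitin gene UBI4, both in the list, were 2.43-fold and 1.64-fold lower. The list call was lost without EC1118 replicate 1 at 15 °C (adjusted p = 0.0515) or replicate 3 at 30 °C (adjusted p = 0.0500). Respiratory chain genes fell in 13 of 42 cases (13 adjusted over the list alone, median -0.28, list test adjusted p = 0.0332, and adjusted p = 0.923 with an estimated correlation), SDH3 by 1.58-fold. That call was lost without EC1118 replicate 1 at 15 °C (median -0.18, adjusted p = 0.185), replicate 2 at 30 °C (0.138) or replicate 3 at 30 °C (0.0500), and the median was -0.43 without replicate 3 at 15 °C. The respiratory list also failed fry (adjusted p = 0.119) and the fit without both arrays that stand apart (adjusted p = 0.0775). Aquaporins and membrane stress proteins fell in 6 of 12 cases (6 adjusted over the list alone, list test adjusted p = 0.0335, and adjusted p = 0.695 with an estimated correlation). The aquaporin AQY2 fell 2.10-fold. That list call was lost with a filter on dim genes (adjusted p = 0.227) and without replicate 3 at 30 °C (adjusted p = 0.0500).

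**Figure D2:**
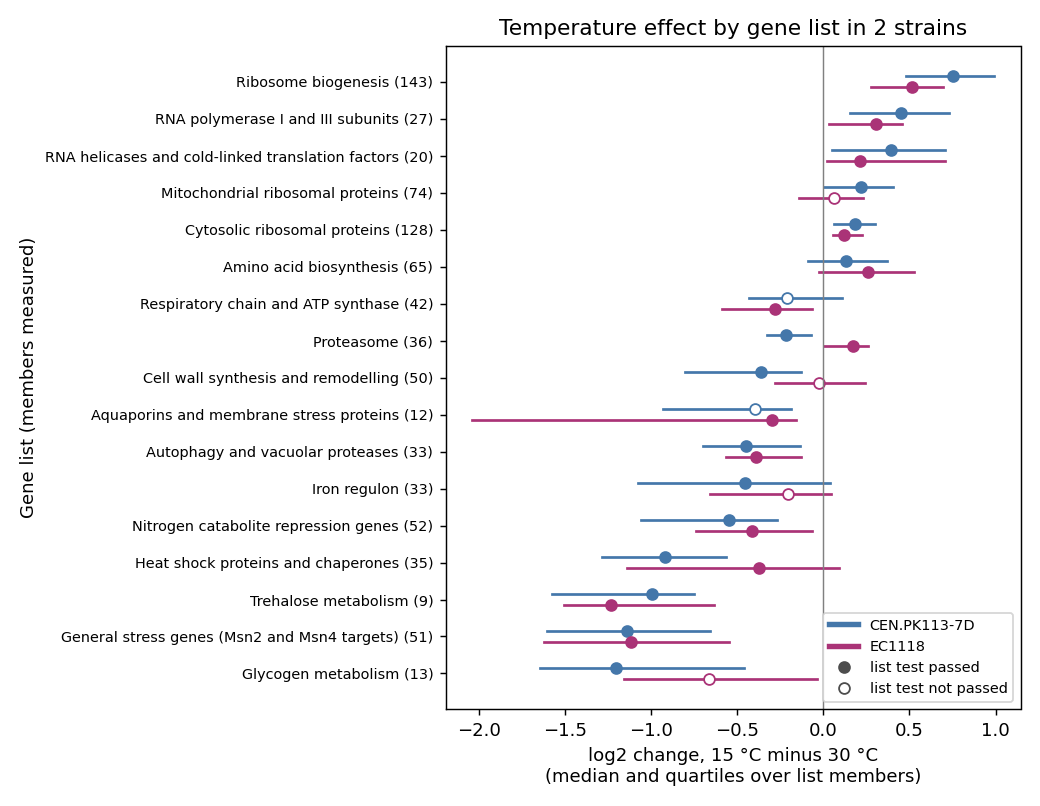
Median log2 change (15 °C minus 30 °C, horizontal axis; bars, quartiles over list members) of the 17 gene lists that passed the list test with the preset correlation in at least 1 strain, in blue for CEN.PK113-7D and purple for EC1118, with filled points where the test passed. Ribosome biogenesis lay at 0.75 and 0.51, and the proteasome list at -0.22 and 0.17, the negative value losing its call with median centring or quantile normalization; none of these list tests passed with an estimated correlation.

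The interaction asked where the temperature effect differed between the strains. FLO11 fell in CEN.PK113-7D in the cold (log2 change -2.98 ± 0.08) and rose in EC1118 (0.75 ± 0.08), a difference of 3.73 ± 0.11 (n = 3 per group, adjusted p = 4.75e-08). The phosphate transporter PHO84 likewise went from 206 ± 79.5 to 37.9 ± 6.33 in CEN.PK113-7D and from 116 ± 16.8 to 269 ± 9.55 in EC1118 (difference 3.61 ± 0.32, adjusted p = 0.000320). DIP5 was 16.0-fold lower at 15 °C in CEN.PK113-7D, and its log2 change of -0.53 ± 0.21 in EC1118 missed the threshold (adjusted p = 0.0569; difference 3.47 ± 0.30, adjusted p = 0.000292). The fall of HXT2 in CEN.PK113-7D stood against a log2 change of 0.93 ± 0.45 in EC1118 that missed the threshold (adjusted p = 0.108; log2 change 1.44, adjusted p = 0.0122, without EC1118 replicate 1 at 30 °C), and the difference passed (adjusted p = 0.00268). AQY1 measured -0.60 ± 0.60 in CEN.PK113-7D and -4.52 ± 0.60 in EC1118 (difference -3.92 ± 0.85, adjusted p = 0.0145; -4.52 without EC1118 replicate 1 at 30 °C). HOP1, a protein of meiotic chromosomes, was at least 6.65-fold higher at 15 °C in CEN.PK113-7D, where it read 79.0 ± 8.22 and 1 of 3 arrays at 30 °C was at the floor. It read between 10.3 and 13.6 on average in EC1118, with 1 array at the floor at each of 15 °C and 30 °C.

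The interaction passed for 710 of 5449 genes, 472 with a more positive and 238 with a more negative temperature effect in EC1118, and 147 differed by at least 2-fold (107 and 40). Quantile normalization gave a split of 369 and 358 in place of 472 and 238. Without EC1118 replicate 1 at 15 °C 468 genes passed. Of the 710 genes, 96 were called in opposite directions in the 2 strains, 200 in the same direction, 233 in CEN.PK113-7D alone and 181 in EC1118 alone. Across all genes, which are not independent, the temperature effects of the 2 strains correlated with r = 0.706 (rho = 0.736), and these contrasts shared no arrays. Both strains called 823 genes higher (288 if the lists were independent) and 1290 lower (598 if independent) at 15 °C.

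Of 36 proteasome genes, 21 had a more positive temperature effect in EC1118 and 0 a more negative one (29 and 0 adjusted over the list alone, median difference 0.40, list test adjusted p = 1.42e-11, and adjusted p = 0.156 with an estimated correlation). The core subunit gene PRE10 had a difference of 0.51 ± 0.07. Cell wall genes differed in the same direction in 19 of 50 cases and oppositely in 1 (26 and 3 adjusted over the list alone, median 0.38, list test adjusted p = 5.01e-07, and adjusted p = 0.156 with an estimated correlation). The glucanase gene EXG2 (1.06 ± 0.10) and DSE1 (1.82 ± 0.17) were among them. For heat shock proteins and chaperones the counts were 12 and 1 of 35 (18 and 1 adjusted over the list alone, median 0.36, list test adjusted p = 1.47e-05, and adjusted p = 0.583 with an estimated correlation). SSA2 had a difference of 0.88 ± 0.11. Genes under nitrogen catabolite repression gave 13 and 2 of 52 (20 and 2 adjusted over the list alone, median 0.29, list test adjusted p = 0.00284, and adjusted p = 0.700 with an estimated correlation), PUT1 at 2.32 ± 0.44. Ribosome biogenesis shifted the other way, with a smaller rise in EC1118: 20 of 143 genes were more negative and 2 more positive (30 and 2 adjusted over the list alone, median -0.27, list test adjusted p = 1.42e-11, and adjusted p = 0.700 with an estimated correlation). NSR1 had a difference of -0.95 ± 0.16. The ribosome biogenesis list did not pass fry (adjusted p = 0.0987). Of 47 lists 10 passed, and without EC1118 replicate 3 at 15 °C 17 passed.

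**Figure D3:**
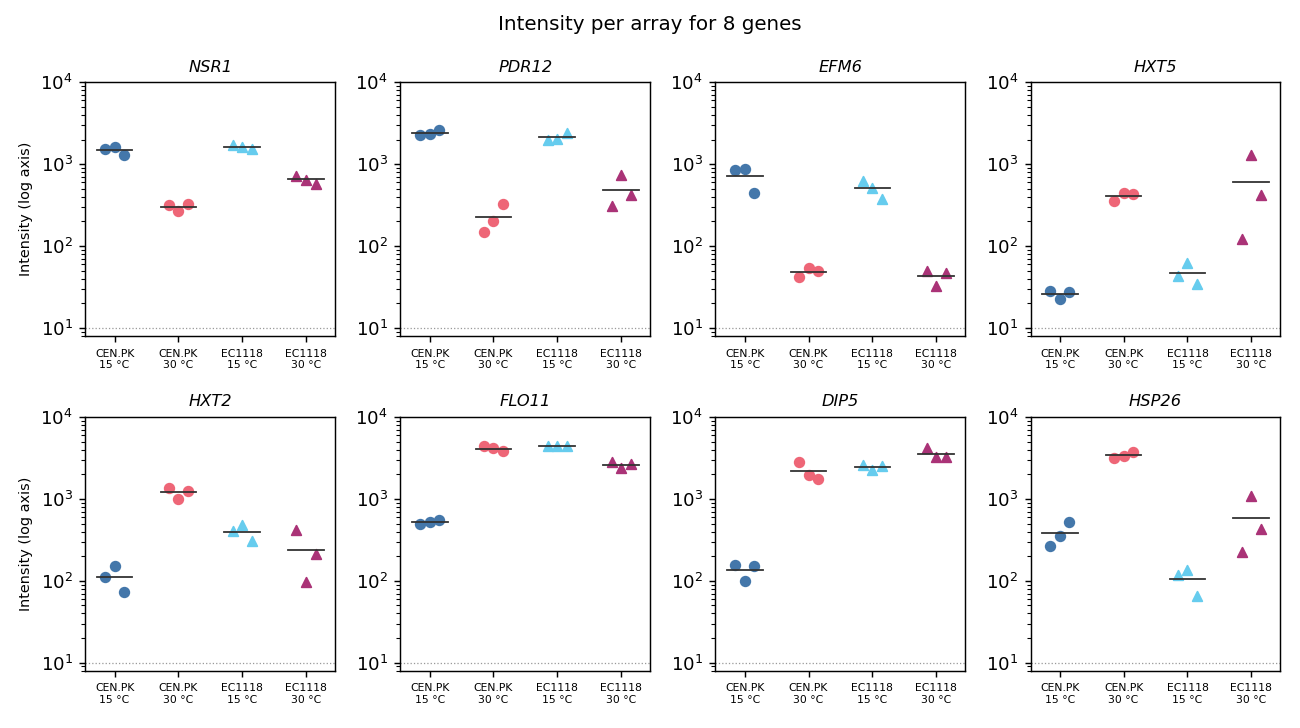
Intensity of 8 genes on each array (vertical log axis; 3 points per group, horizontal bar for the mean, dotted line for the floor of 10). FLO11 was lower at 15 °C than at 30 °C in CEN.PK113-7D and higher in EC1118, and HXT5 and HSP26 were highest in replicate 2 among the EC1118 arrays at 30 °C.

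The strains were then compared at each temperature. STE2, the receptor for alpha factor, read 4244 ± 261 in CEN.PK113-7D and 84.0 ± 7.64 in EC1118 at 30 °C, 50.6-fold lower in EC1118 (log2 change -5.66 ± 0.13, n = 3 per strain, adjusted p = 5.22e-10) and 41.0-fold lower at 15 °C. All 7 a-specific genes were lower in EC1118 at both temperatures (7 adjusted over the list alone at each), among them the pheromone gene MFA2 (98.1-fold at 30 °C) and BAR1, the protease that degrades alpha factor (120.0-fold). That list gave adjusted p = 2.82e-11 at 15 °C and 2.89e-09 at 30 °C, and adjusted p = 0.188 and 0.137 with an estimated correlation. Of 15 haploid-specific genes 12 were lower and 2 higher at 15 °C, and 13 and 2 at 30 °C (13 and 2 adjusted over the list alone at each), with list test adjusted p = 3.88e-12 and 2.34e-09, and adjusted p = 0.188 and 0.137 with an estimated correlation. GPA1, the G protein subunit of the pheromone pathway, was 17.9-fold lower at 30 °C, and RME1, a repressor of meiosis, 8.57-fold lower. FAR1, which arrests the cell cycle in response to pheromone, was at least 79.6-fold lower at 15 °C, with 1 of 3 EC1118 arrays at the floor. IME4, an mRNA methyltransferase of meiosis, was at least 21.0-fold higher in EC1118 at 30 °C, where 2 of 3 CEN.PK113-7D arrays were at the floor.

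Alpha-specific genes were lower in EC1118 at 15 °C in 5 of 5 cases (5 adjusted over the list alone, median -2.51, list test adjusted p = 0.000109, and adjusted p = 0.354 with an estimated correlation). At 30 °C 2 were lower (2 adjusted over the list alone, list test adjusted p = 0.436, and adjusted p = 0.858 with an estimated correlation). In CEN.PK113-7D the alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 were 5.89-fold and 19.1-fold higher at 15 °C than at 30 °C (adjusted p = 0.00286 and 7.32e-05), and 3.78-fold and 11.3-fold higher without replicate 3 at 15 °C. MF(ALPHA)1 measured 505, 776 and 2364 in replicates 1, 2 and 3 there, and MF(ALPHA)2 159, 255 and 967. FIG1, a membrane protein induced by pheromone, read 185, 404 and 1516 on the same arrays. It was at least 46.9-fold lower in EC1118 at 15 °C, at least 26.5-fold without CEN.PK113-7D replicate 3 at 15 °C and at least 75.8-fold without replicate 1, and 2 of the 3 EC1118 arrays were at the floor.

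**Figure D4:**
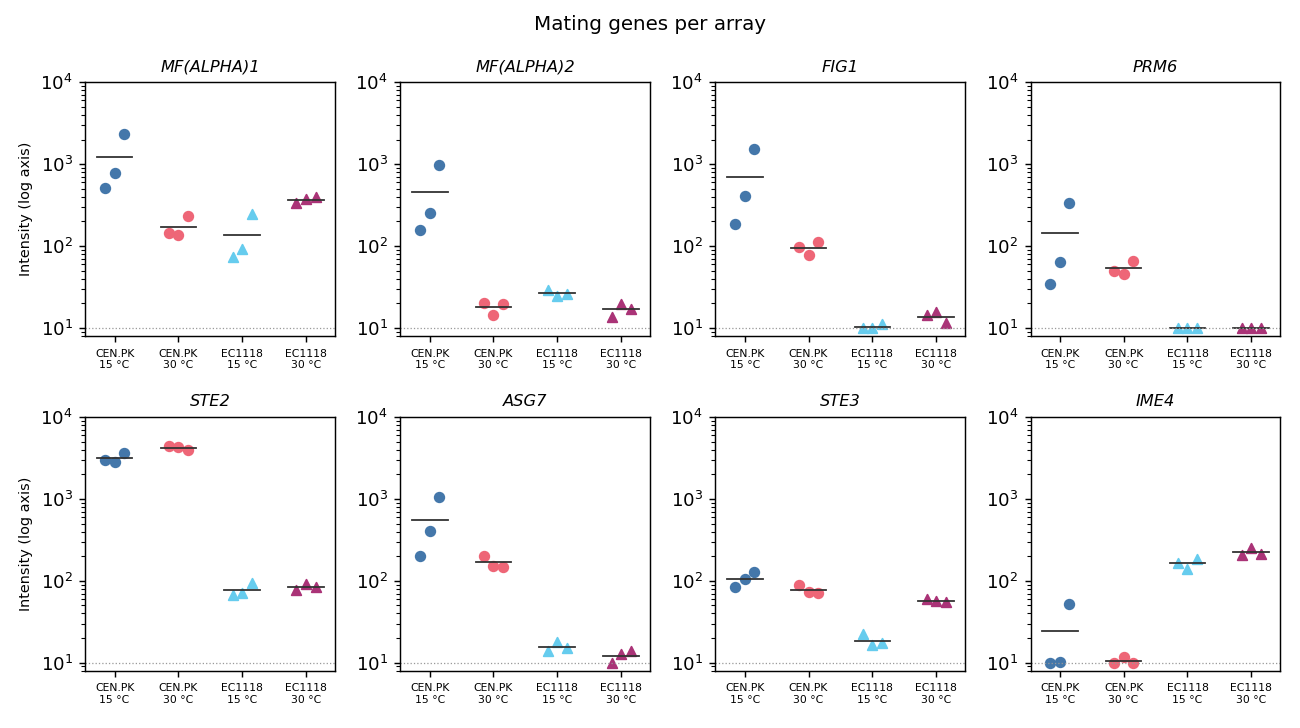
Intensity of 8 mating genes on each array (vertical log axis; 3 points per group from left to right for replicates 1, 2 and 3, horizontal bar for the mean, dotted line for the floor of 10). MF(ALPHA)2 read 967 in CEN.PK113-7D replicate 3 at 15 °C, and STE2 averaged 84.0 in EC1118 at 30 °C.

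Outside the mating genes, ASP3-1, one of the near-identical copies of a cell wall asparaginase that share a probe set, was at the floor on all 6 EC1118 arrays and read 6253 ± 73.3 in CEN.PK113-7D at 30 °C. ASP3-1 was at least 625-fold lower in EC1118 at 30 °C and at least 524-fold lower at 15 °C. The maltose permease MAL11 was at least 93.4-fold lower in EC1118 at 30 °C, and 9 of 11 maltose and isomaltose genes were lower there and 8 at 15 °C (10 and 8 adjusted over the list alone). The list test gave adjusted p = 8.49e-08 at 30 °C and 1.18e-06 at 15 °C, and adjusted p = 0.137 and 0.188 with an estimated correlation. Higher in EC1118 were ADH7, an alcohol dehydrogenase (at least 256-fold at 30 °C), and the low-affinity glucose transporter HXT1 (14.0-fold at 15 °C). At 15 °C ADH7 was at least 34.7-fold higher, with 1 of 3 CEN.PK113-7D arrays at the floor, at least 22.8-fold without EC1118 replicate 1 and at least 65.1-fold without EC1118 replicate 3. PHO5 was at least 66.5-fold higher in EC1118 at 15 °C, and 12 of 25 phosphate genes were higher and 2 lower (14 and 2 adjusted over the list alone, list test adjusted p = 0.00308, and adjusted p = 0.188 with an estimated correlation). The phosphate transporter gene PHO84 was 7.15-fold higher. The kinase gene HAL5 was 16.0-fold and 17.7-fold higher in EC1118 at 15 °C and 30 °C. AQY1 was 26.9-fold higher in EC1118 at 30 °C, and 40.6-fold without EC1118 replicate 1 at 30 °C.

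At 30 °C 34 of 36 proteasome genes were lower in EC1118 and 0 higher (34 and 1 adjusted over the list alone, median -0.54, list test adjusted p = 3.07e-14, and adjusted p = 0.0910 with an estimated correlation). SCL1 and PRE8 of the core particle were among them (-0.80 ± 0.05 and -0.72 ± 0.05). At 15 °C 15 were lower and 1 higher (16 and 1 adjusted over the list alone, median -0.17, list test adjusted p = 7.22e-05, and adjusted p = 0.345 with an estimated correlation). Heat shock proteins and chaperones were lower in EC1118 at 30 °C in 25 of 35 cases and higher in 1 (27 and 1 adjusted over the list alone, list test adjusted p = 2.27e-08, and adjusted p = 0.199 with an estimated correlation). HSP26 was 7.24-fold lower there, and its log2 change of -2.86 ± 0.50 became -3.46 without EC1118 replicate 2. Cell wall genes were lower in 29 of 50 cases at 30 °C and higher in 2 (29 and 2 adjusted over the list alone, list test adjusted p = 9.82e-09, and adjusted p = 0.0910 with an estimated correlation). The chitinase gene CTS1 was 5.97-fold lower. Iron regulon genes were lower in 16 of 33 cases and higher in 4 (18 and 4 adjusted over the list alone, list test adjusted p = 0.0129, and adjusted p = 0.199 with an estimated correlation), FET3 by 4.16-fold. Ribosome biogenesis genes were higher in EC1118 at 30 °C in 85 of 143 cases and lower in 2 (92 and 3 adjusted over the list alone, list test adjusted p = 1.17e-11, and adjusted p = 0.773 with an estimated correlation), NSR1 by 2.14-fold. Trehalose genes were higher in 7 of 9 cases at 15 °C and 6 at 30 °C (7 and 6 adjusted over the list alone), ATH1 by 1.51-fold at 15 °C, with list test adjusted p = 0.00763 and 0.0119, and adjusted p = 0.725 and 0.773 with an estimated correlation.

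Between the strains 1802 of 5449 genes passed the threshold at 15 °C, 1038 higher and 764 lower in EC1118, and 2255 passed at 30 °C, 1146 higher and 1109 lower. With centred arrays the split at 15 °C was 899 higher and 869 lower, and with quantile normalization that at 30 °C was 1369 and 1015. At least 2-fold changes numbered 318 at 15 °C (125 higher, 193 lower) and 396 at 30 °C (122 higher, 274 lower), and values did not overlap between strains for 44.9% and 54.9% of genes, where chance gives 10%. The meiosis list passed at both temperatures with 14 and 23 of 53 genes lower in EC1118 and 4 and 4 higher (5 and 14 at 15 °C and 4 and 26 at 30 °C adjusted over the list alone, higher first). Its adjusted p was 0.00763 at 15 °C and 0.00153 at 30 °C, and adjusted p = 0.725 and 0.773 with an estimated correlation. At 15 °C its median of -0.11 turned to 0.38 with dim genes left out and lay at -0.17, -0.05 and -0.07 without CEN.PK113-7D replicate 2, CEN.PK113-7D replicate 3 and EC1118 replicate 1 at 15 °C. With quantile normalization the meiosis list passed at neither temperature (median 0 at 15 °C and -0.05 at 30 °C, adjusted p = 0.343 and 0.0949). With dim genes left out neither passed (adjusted p = 0.179 and 0.947), and the median at 30 °C went from -0.34 to 0.01. How well the probes match EC1118 sequence was not analysed here.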

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

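The test of EC1118 RNA mixed into an array, the look at probe sequences that differ from EC1118 and the omission of both arrays that stand apart were chosen only after the results they measure were seen. The values that follow are the log2 temperature effect (15 °C minus 30 °C) in EC1118 minus that in CEN.PK113-7D, and each passed the limma test of the difference itself. More positive in EC1118 were HXT2 (4.41), FLO11 (3.73), PHO84 (3.61), YAR068W (3.52), DIP5 (3.47), YNL277W-A (2.90), PHO89 (2.58), SFG1 (2.55), FUI1 (2.46), PUT1 (2.32), ISF1 (1.89), TMA10 (1.78) and SPS4 (0.94). ENA5, on a probe set that shares sequence with near-identical genes, was also more positive (3.003). More negative in EC1118 were AQY1 (-3.92), HOP1 (-3.10), YRO2 (-2.96), COS12 (-2.70), PES4 (-2.42), SPR2 (-2.26), FAR1 (-2.02), YGL262W (-1.72), GIT1 (-1.17) and YCR101C (-0.77). The AQY1 difference was -4.52 without EC1118 30 °C replicate 1.

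Some differences rest on values at or near the floor. PHO5 (2.65) was at the floor on all CEN.PK113-7D arrays, SPO11 (-2.42) on all EC1118 arrays and AZR1 (3.09) on all arrays at 30 °C. At the floor were 2 of 3 arrays at 30 °C in each strain for YCR101C, 1 of 3 EC1118 arrays at 15 °C and 2 at 30 °C for SPR2, 2 of 3 at 15 °C for FIG1 in EC1118 and for YNL277W-A in CEN.PK113-7D. HOP1 had 1 such array in every group but CEN.PK113-7D at 15 °C, YGL262W 1 in CEN.PK113-7D at 30 °C and FAR1 1 in EC1118 at 15 °C. For YMR175W-A 2 CEN.PK113-7D and 3 EC1118 arrays at 15 °C were at the floor. The AZR1 call was lost without CEN.PK113-7D 15 °C replicate 2, CEN.PK113-7D 30 °C replicate 2, EC1118 30 °C replicate 3 (adjusted p from 0.0521 to 0.0605), and its difference was 3.72 without CEN.PK113-7D 15 °C replicate 3. The FIG1 difference (-2.77) held its call without CEN.PK113-7D 15 °C replicate 1 (-3.46) or 3 (-1.95) and was lost with a pseudocount (adjusted p = 0.0896), with trend and robust options (adjusted p = 0.0556), with all probe sets as separate features (adjusted p = 0.0577) and without any of the other 10 arrays (adjusted p from 0.0736 to 0.106). YMR175W-A (-2.34) lost its call without any of CEN.PK113-7D 15 °C replicate 3, CEN.PK113-7D 30 °C replicate 1, CEN.PK113-7D 30 °C replicate 2, EC1118 15 °C replicate 1, EC1118 15 °C replicate 2, EC1118 15 °C replicate 3, EC1118 30 °C replicate 3 (adjusted p from 0.0505 to 0.0840) and with a pseudocount (adjusted p = 0.0596).

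Lists whose temperature effects differed had median differences of 0.36 for heat shock proteins and chaperones, 0.38 for cell wall genes, 0.29 for nitrogen catabolite repression, -0.27 for ribosome biogenesis and -0.22 for RNA polymerases I and III. With an estimated correlation none passed, with adjusted p = 0.583, 0.156, 0.700, 0.700 and 0.502 in that order. Median differences were -0.0542 for cytosolic and -0.15 for mitochondrial ribosomal proteins, and fry did not pass these 2 lists (adjusted p = 0.0740 and 0.180) or ribosome biogenesis (adjusted p = 0.0987). With an estimated correlation these 2 lists had adjusted p = 0.700 and 0.700. Ergosterol synthesis had 0.30, with adjusted p = 0.700 with an estimated correlation. That call was lost without CEN.PK113-7D 15 °C replicate 3 (adjusted p = 0.0662), with quantile normalization (adjusted p = 0.0502) and without both arrays that stand apart (median 0.19, adjusted p = 0.179). Of 402 probe sets with no gene name here, 153 passed the threshold for temperature in CEN.PK113-7D, 150 in EC1118, 108 between strains at 15 °C, 106 at 30 °C and 35 for the interaction.

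Many mating genes read highest in replicate 3 among the CEN.PK113-7D arrays at 15 °C, but the other replicates did not all lack the signal. MF(ALPHA)2 read 159, 255 and 967 in replicates 1, 2 and 3, against 14.4 to 20.2 at 30 °C. Some pheromone-response genes were lower in replicate 3 than at 30 °C, such as PRM2 (341 against 369 to 391) and TEC1 (688 against 873 to 944). The comparisons of replicates below are within 15 °C. For alpha-specific genes the median difference of temperature effects was -2.08 (list test adjusted p = 8.00e-05, and adjusted p = 0.502 with an estimated correlation). That median did not rest on CEN.PK113-7D replicate 3 at 15 °C alone, since the list had a median temperature effect of -0.97 in EC1118 and 0.73 in CEN.PK113-7D. In EC1118 STE3 read 16.5 to 22.2 at 15 °C and 55.1 to 59.5 at 30 °C. Without CEN.PK113-7D replicate 3 at 15 °C the differences of MF(ALPHA)1 (-4.20) and MF(ALPHA)2 (-3.60) became -3.56 and -2.84. A shift of the whole array was argued against by a median deviation of 0.81 over 16 pheromone-response genes not looked at before, where 99% of 10000 matched random lists lay below 0.23, and EC1118 RNA in the array by 17 of 28 alpha-specific and pheromone genes that were higher there than on any other array, against 9.58% of all genes (8 of the 16, the other 12 being those on which the pattern was found). IME4, at 52.5 there against 10.0 and 10.2 in the other replicates and 164 on average in EC1118, had the middle level that EC1118 RNA would give, at a share of 27.5%, but of 7 other genes dim in those 2 replicates and bright in EC1118 0 reached a 0.5 fraction of the level which that share needs (PHO5 10.0 against 208). As a hypothesis, cells of both mating types may have been present in that culture: 15 of the 16 genes were above both other replicates, against 47.0% of all genes. STE3, the receptor gene of alpha cells, was 1.35-fold and AFB1 1.21-fold above the other replicates, while ASG7 was 3.75-fold, so the hypothesis stays open.

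Proteasome genes had a median difference of temperature effects of 0.40, with a lower quartile of 0.32. The scale of the arrays was argued against by a median of 0.36 with centred arrays, and a single array by a lowest median of 0.36, without EC1118 30 °C replicate 3. Probe sequences that lower the EC1118 signal by a fixed log2 amount would cancel in the difference of temperature effects. In EC1118 the median log2 intensity of the list per array was 10.04 to 10.12 at 15 °C and 9.98 to 10.00 at 30 °C. In CEN.PK113-7D it was 10.22 to 10.28 and 10.50 to 10.58. A fixed mismatch cancels whatever these values are, so they do not test a role of the probes in the difference. Such a mismatch could still lower the levels in EC1118, and mismatch of other kinds was not tested. The match of the probes was not measured. A strain difference in the temperature response of these genes stays open as a hypothesis, and the list test gave adjusted p = 0.156 with an estimated correlation.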

How the results depend on the processing

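The omission of both arrays that stand apart was chosen only after the results were seen. Counts are given in the order temperature in CEN.PK113-7D, temperature in EC1118, strain at 15 °C, strain at 30 °C and interaction. Of 385 called gene results, 362 kept their direction and call under all 23 settings that gave them a value, and of 67 list results 51 did so under 22 settings, the estimated correlation aside. With an estimated correlation 0, 0, 0, 0 and 0 lists passed, and with fry 37, 24, 24, 27 and 18. Changes of at least 2-fold numbered 297, 248, 130, 196 and 72 with the filter on dim genes, which tests 1260 fewer genes, and 272, 225, 194, 258 and 79 with a pseudocount, which shrinks the folds of dim genes. The meiosis list at 15 °C had a median of -0.11 and reversed to 0.38 with the filter on dim genes, and the cause was not tested. With 1 array left out, genes past the threshold ranged over 2736 to 3247, 2541 to 3071, 1357 to 1803, 1833 to 2435, 468 to 794, at least 2-fold changes over 423 to 567, 353 to 466, 312 to 335, 381 to 412, 133 to 166 and lists over 15 to 16, 10 to 15, 12 to 17, 14 to 16, 10 to 17. The 468 interaction genes came without EC1118 15 °C replicate 1 and the 17 interaction lists without EC1118 15 °C replicate 3. Without both arrays that stand apart, 3187, 2719, 1727, 2053 and 742 genes passed, 574, 360, 336, 384 and 172 at least 2-fold, and 15, 12, 16, 15 and 14 lists. Same-numbered arrays deviated together (correlation above 0.1) in 11 of 18 pairs (-0.24 to 0.48), among them all 6 pairs of replicate 1 (0.34 to 0.48), and 8 of 12 arrays lay closest to their own number. Between the strains at 15 °C all 3 pairs were above 0.1, and in no other comparison were all 3. The replicate block gave 3301, 3098, 1909, 2400 and 783 genes and 15, 13, 15, 15 and 14 lists, and kept every call of a named gene or list between the strains at 15 °C. Under the block RPS9B missed the threshold for the interaction (adjusted p = 0.0502), as it did without each array but CEN.PK113-7D 15 °C replicate 3 (adjusted p from 0.0568 to 0.0882), and PUT4 passed it for temperature in both strains (adjusted p = 0.0362 and 0.0435), as it did in CEN.PK113-7D without 15 °C replicate 3 (adjusted p = 0.00865). After the values were seen, 38 panel results that missed the threshold in the strain and interaction comparisons were left out of these counts. Over 844 values of theirs, 44 changed sign, 0 of them past the threshold, and 27 passed it. Genes near the floor limit what these arrays resolve, with 46 probe sets at the floor on all 12 arrays.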

Other observations

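No test in this part was chosen after the result it measures was seen, but the 3 lists below were picked for description, with members of small adjusted p, after their values were seen. The alternatives were not run on the genes DAN4, TIR3, SNF3, ADH5 and GPM2. None of the 3 lists passed the list test for temperature in either strain. The cell wall mannoprotein gene DAN4 fell 7.37-fold (log2 change -2.88 ± 0.88, n = 3) in CEN.PK113-7D, and TIR3 fell 2.35-fold. Of 8 TIR and DAN genes 0 rose and 3 fell in CEN.PK113-7D, and 0 rose and 0 fell in EC1118 (0 and 0, and 0 and 0, adjusted over the list alone). The list test gave adjusted p = 0.745 and 0.613, and adjusted p = 0.933 and 0.977 with an estimated correlation. The glucose sensor gene SNF3 fell 2.71-fold in CEN.PK113-7D and 1.96-fold in EC1118. Of 18 hexose transporter and sensor genes 3 rose and 7 fell in CEN.PK113-7D, and 3 rose and 6 fell in EC1118 (3 and 7, and 3 and 6, adjusted over the list alone). The list test gave adjusted p = 0.745 and 0.613, and adjusted p = 0.854 and 0.918 with an estimated correlation. The alcohol dehydrogenase gene ADH5 rose 2.26-fold and 3.02-fold, and GPM2, a paralogue of phosphoglycerate mutase, fell 2.76-fold and 2.13-fold. Of 29 glycolysis and ethanol formation genes 3 rose and 12 fell in CEN.PK113-7D, and 6 rose and 6 fell in EC1118 (3 and 11, and 6 and 6, adjusted over the list alone). The list test gave adjusted p = 0.745 and 0.955, and adjusted p = 0.933 and 0.977 with an estimated correlation.

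In 12 genes the signal was at the floor on all 6 arrays of 1 strain and averaged at least 100 in both groups of the other. YIL014C-A, PRM8, MAL11, ASP3-1, YLR156W, BDS1, YOL163W, YOL162W and FEX2 were bright in CEN.PK113-7D, and PHO5, RDS1 and AIF1 in EC1118. Of the 12, 0 belonged to the mating-type, haploid-specific or meiosis lists, but this count cannot decide whether mating type and ploidy were a cause. Listed genes such as STE2 (67.5 to 92.9) and BAR1 (13.9 to 29.1) read above the floor in EC1118, so the filter left them out. PRM8, known as pheromone-regulated, is in none of these lists. As a hypothesis, blocks of genes that differ between the strains may account for part: 5 of the genes (ASP3-1, YLR156W, BDS1, YOL163W and YOL162W) lay next to another such gene, against a highest count of 4 in 10000 random sets. Of the 12, 2 were on shared-sequence probe sets, ASP3-1 and YLR156W. Both are among the 5, so these neighbours may not be independent signals. Absence of a gene, probes that do not match it and silencing were not separated.

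Other splits of the arrays were compared with the real one. For the 4 pairwise comparisons the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real and highest other counts of genes were 3185 against 2, 2953 against 0, 1802 against 1, 2255 against 0, and of genes changed at least 2-fold 476 against 0, 414 against 0, 318 against 0, 396 against 0. For the interaction 1 of 82 splits, the real one, gave as many genes (710 against 1) and as many changed at least 2-fold (147 against 1). In every other split of any comparison the real difference enters the residual spread, which lowers the gene counts. Part of it also stays between the groups compared. The other splits therefore do not show what chance alone gives, and these gene counts cannot exclude chance. For lists the real and highest other counts were 15 against 22, 13 against 17, 14 against 21, 15 against 17, with as many in 6, 3, 4 and 4 of the 10 splits. For interaction lists 48 of 82 splits gave as many (10 against 23). These numbers of splits include the real one. For the lists of any comparison chance cannot be excluded.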
